A study of Mus musculus with 58 samples.

How the data were processed

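The series holds 58 samples, of which 18 are RNA-seq samples and 40 are CUT&RUN chromatin samples. The CUT&RUN samples were not analysed here. RNA was measured in fully grown oocytes (FGO), morulae and extraembryonic ectoderm (ExE), with the SMART-Seq v4 cDNA kit and Nextera XT libraries per the labels' protocols; this library chemistry does not mark the strand of a transcript. The count table used here has 24077 genes and 24 columns for 14 libraries. The 4 RNA samples of reciprocal B6 and PWK morulae have no column in it, so the comparisons planned with them were not used here.

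The deposited table holds raw counts per gene, per the file headers. For the FGO libraries it gives 1 column of counts per library. For the morula and ExE libraries it gives 1 column of maternal and 1 of paternal counts, per the file headers, and the strain labels name a B6.129 mother and a PWK father. The design written beforehand assumed 1 total per library; maternal and paternal counts were therefore summed for the tests of expression, and such sums leave out reads that cannot be assigned to a parent. The submitters' processing notes list bcl2fastq 2.17, Trim Galore 0.6.4, Bowtie2 2.3.5, deepTools 3.3.1, STAR 2.7.3, RSEM 1.3.1, MACS2 2.1.2 and bedtools 2.26.0 with the builds mm10 and dm6 for the whole series. Which of these tools made the counts, the annotation, the rule that assigned reads to a parent and the treatment of reads with several matches are not given in the sources used here. Counts of paralogs, overlapping genes and antisense partners such as Xist and Tsix are therefore uncertain.

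Gene symbols were matched to the mm10 annotation of the GRCm38.p6 release, 23975 by symbol and 81 by synonym, and 21 stayed unmatched. No count was found in any library for 4157 genes. Totals were 19805264 to 26364085 counts in FGO libraries, 1299715 to 1685510 in morula libraries and 3397585 to 4361832 in ExE libraries. A floor of 3 counts corresponds to 0.114 to 0.151 CPM in FGO, 1.78 to 2.31 in morulae and 0.688 to 0.883 in ExE. Intervals of shares of reads are 95% exact Clopper-Pearson intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

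Knockout libraries were compared with control (CTR) libraries of the same stage, with libraries grouped by their labels. Each comparison used edgeR 4.0.16 with TMM factors, filterByExpr and the robust quasi-likelihood F test, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values of knockout over control, with standard errors (SE) from the same fit. The common biological coefficient of variation was 0.201 in FGO, 0.178 in morulae and 0.212 in ExE. Differences of the effect between stages were tested as an interaction term in 1 fit of both stages. The 31 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of 1 comparison with at least 3 tested members. List members removed by filterByExpr were not tested. A member near silent in CTR passes that filter only where it is higher in the knockout, which favours rises in such lists. Overlaps of called genes were tested with Fisher's exact test, two-sided. Shares of reads were compared with two-sided exact permutation tests, which cannot go below p = 0.333 with 2 against 2 libraries or p = 0.0667 with 2 against 4.

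These comparisons, lists, the rule for the genes named in the text and 74 alternatives were fixed before the data were examined. For morulae the plan had the reciprocal-cross libraries share the estimate of the spread, in that comparison and in both differences between stages. They have no column here, so those fits took only the 4 CTR and matKO libraries from morulae. The rule names Pcgf1, Pcgf6 and 6 imprinted genes in each comparison. It adds the 10 called genes with the largest rise and the 10 with the largest fall that reached a mean of 5 CPM and whose groups did not overlap, leaving out clone names and unnamed gene models. It also takes up to 4 members of each list with the smallest p, and 5 genes for each difference between stages. Some genes that the rule picks are not reported here. The analysis of the parental alleles was chosen after the columns were seen. It used edgeR on maternal and paternal counts with a term for each library, a term for the allele and an allele-by-genotype term. The offsets were the autosomal totals of each allele, and genes had a mean of at least 20 reads. X-linked genes were left out of this test in ExE. Positive values mean a shift towards the paternal allele.

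The expression test of each stage, the allelic test and camera were tried on simulated data with known changes; the other tests were not. In FGO, with 13246 genes in the step, 50.0% of genes changed by 2-fold and 89.9% changed by 4-fold were recovered, with 16 false calls among 155. In morulae, with 8801 genes, the shares were 36.7% and 75.0%, with 10 false calls among 121. In ExE, with 8209 genes, they were 38.8% and 85.9%, with 7 false calls among 130. The allelic test recovered 75.0% of 4-fold and 90.7% of 16-fold changes in morulae, with 7542 genes in the step and 21 false calls among 184. In ExE it recovered 85.0% and 93.9%, with 6811 genes and 6 false calls among 184. In camera, 1, 0 and 0 of 50 unchanged lists of 20 genes in FGO, morulae and ExE gave an unadjusted p under 0.05. The simulated genes varied independently of each other. This trial therefore cannot show how often camera falsely calls lists whose genes vary together.

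The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a mean of at least 1 CPM, a fold change of at least 2, all 14 libraries in 1 fit, a block for the replicate number, no X-linked and Y-linked genes, and each replicate left out. Alternatives added after the data were seen used only paternal or only maternal counts, left out a part of chromosome 8 or single ExE libraries, or changed the offsets, the minimum of reads or the tool of the allelic test. A block for sex from Y-linked reads was not run, since those reads carry no allele counts. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.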

Results

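RNA was sequenced from mouse oocytes, morulae and extraembryonic ectoderm (ExE), the trophoblast tissue beside the epiblast, with and without Pcgf1 and Pcgf6. Both genes encode subunits of variant Polycomb repressive complex 1 (PRC1), which ubiquitinates histone H2A. Fully grown oocytes (FGO) gave 2 control (CTR) and 2 double knockout (KO) libraries. Morulae gave 2 CTR and 2 maternal knockout (matKO) libraries, and ExE gave 2 CTR and 4 matKO libraries. Morulae and ExE came from B6.129 mothers and PWK fathers, per the labels, so that reads over strain variants tell the parental alleles apart. Total counts were 26364085 and 25716758 in FGO CTR and 22008470 and 19805264 in FGO KO. Allele-assigned totals were 1685510 and 1587445 in morula CTR and 1299715 and 1347826 in morula matKO. They were 4219202 and 4361832 in ExE CTR and 4090661, 4002733, 3702226 and 3397585 in ExE matKO.

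Marker genes differed between the 3 stages. FGO levels come from whole-gene counts, while morula and ExE levels count only reads assigned to a parent. A gene whose reads cannot be assigned stands at 0 there whatever its expression, so the levels are not strictly comparable. The median level of the oocyte genes was 1278 to 1364 CPM in FGO libraries, 0.593 to 1.54 CPM in morulae and 0 in ExE. Pluripotency genes had medians of 43.9 to 66.4 CPM in morulae against 0.525 to 5.45 in FGO and 0.459 to 2.25 in ExE. Trophectoderm genes had medians of 43.5 to 71.8 CPM in morulae, 15.9 to 29.8 in ExE and 1.29 to 3.14 in FGO. Trophoblast stem cell and ExE genes had medians of 9.40 to 69.5 CPM in ExE, 7.69 to 17.3 in morulae and 0.389 to 3.20 in FGO. Genes of the 2-cell stage had medians of 0 in ExE and of at most 0.0948 CPM in FGO and 0.385 CPM in morulae.

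The FGO comparison asks which genes the oocyte keeps silent with these PRC1 subunits. Pcgf1 (chromosome 6, 83077552 to 83080855, mm10) fell from 1450 and 1144 CPM in CTR to 31.4 and 23.7 CPM in KO, a log2 change of −5.56 (SE 0.24, adjusted p = 2.0e-05). Pcgf6 fell from 427 ± 26.7 to 194 ± 48.8 CPM (SD, n = 2 each), a log2 change of −1.14 (SE 0.19, adjusted p = 0.0102). The largest rises by fold change were of genes near silent in CTR oocytes, which a ranking by fold change favours. Mt1, a metallothionein that binds zinc, rose from 2.78 ± 0.384 to 377 ± 29.4 CPM (log2 7.08, SE 0.20, adjusted p = 2.1e-06). Rbm46, a germ cell RNA-binding protein, rose from 0.676 to 68.97 CPM (log2 6.66, SE 0.23). Irx2, a patterning homeobox gene, had 0 counts in CTR and 284 in KO, at least 109-fold higher against a floor of 3 counts over the group.

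Of 13459 genes tested with edgeR, 720 rose and 252 fell, and 2897 had an unadjusted p under 0.05. Among the other large rises, Adcy2, an adenylate cyclase, went from 1 to 744 counts (ratio 860, 95% exact interval 154 to 34020). Hoxd1 went from 1 to 389 counts (ratio 450, 80.2 to 17809) and Amigo2, a neuronal adhesion protein, from 2 to 581 counts (ratio 336, 92.6 to 2780). Snx24, Zfp711 and Tbl1x, the last a subunit of a corepressor complex, rose by log2 6.55, 6.45 and 6.31. The largest falls after Pcgf1 were Ddx60 (log2 −4.11, SE 0.38), an antiviral helicase, Mdga2 (−3.52, SE 0.42) and Slc17a6 (−3.49, SE 0.42), a vesicular glutamate transporter. Cyp2c69, Klk15, Cldn15, Fate1, Reg3g and Plxdc2 fell by 3.12 to 2.60 on the log2 scale. The groups did not overlap for 7066 genes (52.5%), where chance gives 33.3% for a single gene. Genes of a library vary together, so the share cannot be set against that rate as a test. Without KO replicate 2 the count was 2029 (1078 rises and 951 falls), of which 866 were among the 972, and the other leave-outs gave 767 to 787. The genes named in FGO that lost their call without 1 of the libraries were Adcy2, Amigo2, Bmp7, Cdkn1a, Fgf5, Hspb1, Id2, Klk15, Plac1, Plk2, Sesn1, Sox2, Syce1, Tfap2c, Wnt7a and Zfp36.

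**Figure D1:**
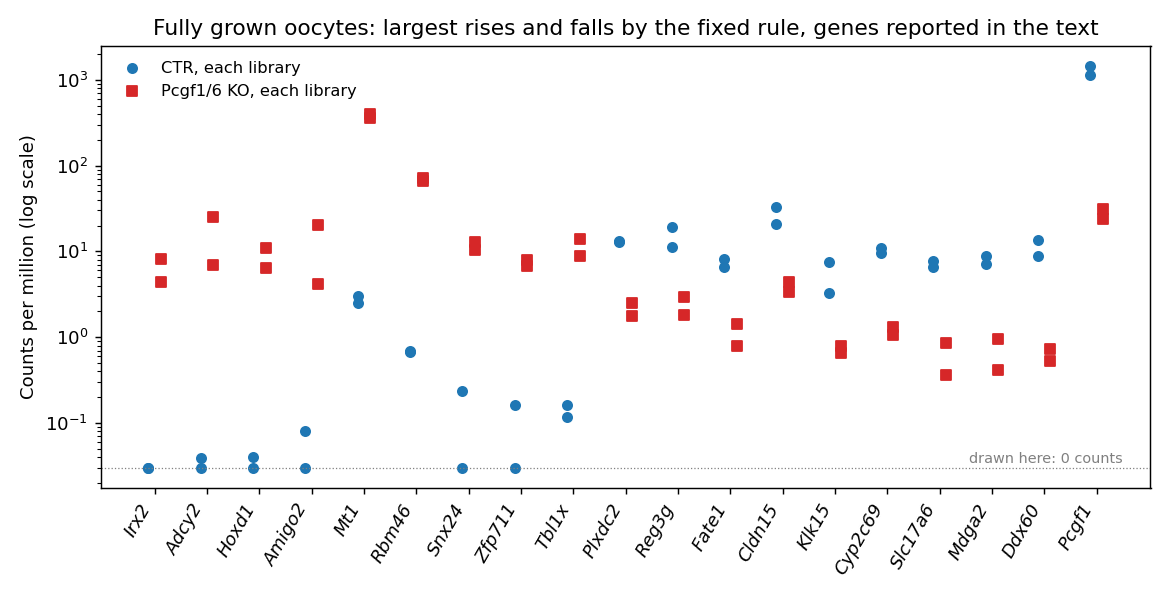
Normalised expression (CPM, log axis) of the reported genes with the largest rises and falls in FGO, with blue circles for the 2 CTR and red squares for the 2 KO libraries. Libraries without a count sit on the dotted line, and Mt1 lies at 2.78 CPM on average in CTR and 377 in KO.

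Some developmental regulators that Polycomb is known to silence rose, but no list of them kept its camera call with an estimated correlation. The lists held 39 Hox genes, 155 other developmental transcription factors and 65 signalling genes found in the data. Members with too few counts were not tested. A member near 0 in CTR is tested only if it is higher in KO, so it can rise but not fall. Of 12 Hox genes tested, 7 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of log2 3.51 and Hoxd8 (4.73) and Hoxd9 (3.60) among them (camera adjusted p = 4.4e-11, and adjusted p = 0.477 with an estimated correlation). Of 52 other developmental transcription factors, 22 rose and 1 fell (31 and 2 adjusted over the list alone). Shox2, a limb and heart regulator, rose by 3.66 and Osr2, a palate regulator, by 1.85 beside Irx2 (median 1.56, adjusted p = 8.8e-18, and adjusted p = 0.477 with an estimated correlation). Of 24 signalling ligands and receptors, 7 rose and 0 fell (9 and 0 adjusted over the list alone), among them the axon guidance ligand Slit2 (3.23), Bmp7 (3.45), Wnt7a (1.45) and Fgf9 (1.02). Their median was 0.54 (adjusted p = 0.00173, and adjusted p = 0.725 with an estimated correlation). Markers of another tissue, epiblast and nascent mesoderm, had positive changes in the same libraries. All 8 were positive and 2 passed, with a median of 0.66 (adjusted p = 0.00293, and adjusted p = 0.581 with an estimated correlation). The 2 that passed were Fgf5 (3.93) and Pou3f1, a neural factor with 0 counts in CTR and at least 48.9-fold more in KO. For markers of granulosa cells, which surround the oocyte, the median of 16 was 0.11 (adjusted p = 0.849), and Nr2f2 alone rose (1.79).

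Some of the genes reported as imprinted through maternal H3K27me3, the Polycomb mark, rose in the KO oocytes too. Sfmbt2, a Polycomb gene needed for the placenta, went from 4 to 85 counts (log2 4.50, SE 0.69, adjusted p = 0.00687). Gab1, an adaptor of growth factor receptors, had 0.340 CPM in CTR and 1.33 in KO and did not pass (log2 1.97, SE 0.60, adjusted p = 0.089). Jade1, Slc38a4, Smoc1 and Xist had too few counts in FGO to be tested. In the wider list of 25 such genes, 10 rose and 0 fell (16 and 2 adjusted over the list alone), with a median of 1.97 (adjusted p = 8.4e-12, and adjusted p = 0.477 with an estimated correlation). Examples were Sall3 (6.00), Hes1 (3.84), a target of Notch signalling, Rbms1 (3.50) and Bbx (2.59). The list was fixed beforehand, and not every member was mainly paternal in these data. In CTR morulae Bbx had 15.9% and 7.14% maternal reads and Hes1 49.3% and 45.5%. Of 38 genes imprinted through DNA methylation, 4 rose and 0 fell: Ascl2 (4.75), Zdbf2 (4.19), Igf2 (4.06) and Phlda2 (2.79). As a list these had a median of −0.03 and a mean of 0.48, and camera did not call it (direction up, adjusted p = 0.196).

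Some germ-line and placental genes rose as well. Of 41 germ-line and meiosis genes reported as PCGF6 targets, 9 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.0112, and adjusted p = 0.868 with an estimated correlation). Meioc (4.3), Taf7l (4.10), and the synaptonemal complex genes Syce1 (3.36) and Sycp3 (1.76) rose. Of 16 trophoblast stem cell and ExE genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Dusp6 (5.23), Sox2 (3.40), Tfap2c (1.23) and Id2 (0.99) as examples. Their median was 0.48 (adjusted p = 0.0018, and adjusted p = 0.477 with an estimated correlation). Of 11 genes of the ectoplacental cone and spongiotrophoblast, 6 rose and 2 fell, the same number adjusted over the list alone, with a median of 0.86 (adjusted p = 2.4e-05, and adjusted p = 0.477 with an estimated correlation). Ascl2, Fosl1 (3.65), Phlda2 and Plac1 (2.04) rose, and Psg17 (−1.68) and Ceacam12 (−1.11) fell. Of 12 genes of the 2-cell stage, Zscan4d fell (−2.47, adjusted p = 0.00773), while its paralogs Zscan4c (−1.92) and Zscan4a (−1.81) did not pass. Adjusted over the list alone 0 rose and 3 fell, and the median was −0.31 (adjusted p = 0.0319, and adjusted p = 0.477 with an estimated correlation). Reads can be shared among these near-identical genes, so the split between them is uncertain.

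Some stress genes rose in the same libraries. Of 19 p53 response genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Cdkn1a (2.14), Sesn1 (2.00), Plk2 (1.62) and Btg2 (1.36) as examples and a median of 0.79 (adjusted p = 4.2e-04, and adjusted p = 0.477 with an estimated correlation). Of 18 immediate early and dissociation stress genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone), with Gadd45b (2.52), Jund (2.08), Zfp36 (1.74) and Hspb1 (1.18). Their median was 0.90 (adjusted p = 0.00173, and adjusted p = 0.851 with an estimated correlation). Over the 11 lists called, adjusted p was 0.477 to 0.868 with an estimated correlation and 0.0442 to 0.336 by fry.

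The other 17 lists were not called in FGO (adjusted p = 0.170 to 0.985). Among 32 PRC1 subunits, Bcor (2.69), a partner of PCGF1, Bcorl1 (1.25) and Pcgf5 (1.02) rose beside the falls of Pcgf1 and Pcgf6. Among 12 PRC2 subunits and 18 genes of the DNA methylation machinery 0 were called. Of 50 oocyte genes, the transcription factor genes Sohlh1 (7.39) and Sohlh2 (3.71) rose and Oog2 (−0.78) fell. Klf5 (5.40), Klf4 (3.25) and Sox2 rose among 16 pluripotency genes. Of 18 trophectoderm genes 4 rose and 3 fell, and of 481 X-linked genes 40 rose and 13 fell. The remaining lists had at most 3 calls each: primitive endoderm, giant cell, labyrinth, visceral endoderm, decidua, blood, proliferation and ribosomal protein genes.

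The morula comparison asks what remains of this effect in embryos with a maternal knockout of both genes. Chka, a choline kinase, rose from 196 ± 20.1 to 466 ± 56.3 CPM (SD, n = 2 each; log2 1.25, SE 0.13, adjusted p = 0.0373). Bbx, one of the imprinted genes with maternal H3K27me3, rose from 203 ± 38.3 to 454 ± 20.6 CPM (log2 1.16, SE 0.14, adjusted p = 0.0490). Dsc2, a desmosomal cadherin, fell from 274 to 2 counts (ratio 0.0093, 95% exact interval 0.0011 to 0.0338, adjusted p = 0.0104). Dppa1 fell from 306 ± 18.4 to 90.5 ± 26.2 CPM (log2 −1.76, SE 0.20, adjusted p = 0.0399). The other named falls were Ccdc160 (−2.82), Sft2d2 (−2.76), Tmem171 (−2.20), Akr1e1 (−1.58), Ugdh (−1.36), a glucuronate-forming enzyme, Oxct1 (−1.34), which breaks down ketone bodies, and Cpne8 (−1.06).

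For the targeted genes, Pcgf1 had at most 4 allele-assigned reads per morula library and checks nothing here. Pcgf6 had 218 ± 29.5 CPM in CTR and 212 ± 11.9 in matKO (log2 −0.04, SE 0.14, adjusted p = 0.915), with both alleles counted. Of 9063 genes tested with edgeR, 2 rose and 10 fell, and 1791 had an unadjusted p under 0.05. With DESeq2 size factors 15 rose and 39 fell, and the DESeq2 Wald test called 82 and 126. The groups did not overlap for 4848 genes (53.5%), where chance gives 33.3% for a single gene, and this share is no test either. Without CTR replicate 1 edgeR called 7 genes, 6 of them among the 12, and Sft2d2, Tmem171, Dppa1, Akr1e1, Oxct1 and Cpne8 were lost. Without X-linked and Y-linked genes, Bbx, Sft2d2, Oxct1 and Cpne8 lost their call. Without CTR replicate 2, matKO replicate 1 or matKO replicate 2 it called 256, 192 and 524, with 12 shared each.

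The trophectoderm list and the trophoblast stem cell and ExE list, of the lineage that forms the placenta, had negative medians in matKO morulae. For the trophectoderm list the matKO libraries lay apart, at a median of 43.5 CPM in replicate 1 and 63.8 in replicate 2, against 71.8 and 67.4 in CTR. Of 18 trophectoderm genes, Dppa1 fell and 0 rose over all genes, and 0 rose and 8 fell adjusted over the list alone. The median log2 change was −0.73 (adjusted p = 2.0e-07, and adjusted p = 0.544 with an estimated correlation). Eomes, a trophoblast T-box factor, had a log2 change of −2.37 (SE 0.31, adjusted p = 0.0510), Tspan8 of −1.21 and the keratin gene Krt18 of −0.78. The 15 trophoblast stem cell and ExE genes had a median of −0.23, with 0 rises and 2 falls adjusted over the list alone (adjusted p = 0.0331, and adjusted p = 0.544 with an estimated correlation). Sox2 (−1.89), Wnt7b (−1.31) and Id2 (−0.84) had its smallest p besides Eomes. The 10 primitive endoderm genes had a median of −0.49, with 0 rises and 2 falls adjusted over the list alone (adjusted p = 0.0418, and adjusted p = 0.544 with an estimated correlation). Pdgfra (−1.46), Sparc (−1.17) and Col4a1 (−0.69) were not called over all genes. The 6 epiblast and mesoderm markers had a median of −0.48, with 0 rises and 2 falls adjusted over the list alone (adjusted p = 0.0331, and adjusted p = 0.544 with an estimated correlation), Dnmt3b (−0.84) among them. Eomes is on this list as well as on both trophoblast lists, so the lists are not separate. The 16 pluripotency genes were not called (median 0.10, mean −0.03, direction up, adjusted p = 0.474).

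Other lists were higher in matKO morulae. Of 24 germ-line and meiosis genes 20 were positive, with a median of 0.55, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 7.8e-04, and adjusted p = 0.544 with an estimated correlation). Ddx4, the germ cell helicase, had a log2 change of 1.72 (SE 0.32, adjusted p = 0.0743), Sycp1 of 1.47, Majin of 0.85 and Sycp3 of 0.48. The 26 imprinted genes of the wider H3K27me3 list had a median of 0.18; Bbx rose over all genes, and 5 rose and 0 fell adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.544 with an estimated correlation). Gramd1b (2.12) and Rftn2 (1.09) had the smallest p after Bbx and did not pass over all genes. Maternal shares in CTR morulae were 16.7% and 32.0% for Gramd1b, from 1 and 8 maternal reads, and 87.8% and 72.7% for Rftn2. Of 11 genes of the 2-cell stage 10 were positive (median 0.40), with Pramel7 (0.40) and Pramel6 (0.25), and 1 rose and 0 fell adjusted over the list alone (adjusted p = 0.0418, and adjusted p = 0.627 with an estimated correlation). Ribosomal protein genes had a positive median (0.21 over 72 genes, with Rps26 at 0.47), with 0 calls over all genes or adjusted over the list alone (adjusted p = 0.00415, and adjusted p = 0.741 with an estimated correlation). Immediate early genes did too (median of 9 genes 0.44), with Socs3 (2.82), Gadd45b (1.22) and Fos (1.02), and 4 rose and 0 fell adjusted over the list alone (adjusted p = 0.00862, and adjusted p = 0.544 with an estimated correlation). Over the 9 lists adjusted p was 0.544 to 0.741 with an estimated correlation and 0.205 to 0.391 by fry, and the other 17 were not called (adjusted p = 0.121 to 0.987).

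In total expression the imprinted genes of the core list did not pass in morulae. Log2 changes were 0.45 for Jade1, 0.26 for Gab1, −0.10 for Smoc1, −0.27 for Sfmbt2 and −0.74 for Slc38a4, an amino acid transporter gene. Xist, the RNA that silences an X chromosome, had 214 and 116 CPM in CTR and 584 and 546 CPM in matKO (log2 1.77, SE 0.24, adjusted p = 0.0555). Xist overlaps its antisense partner Tsix, and unstranded reads cannot tell them apart.

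The parental alleles of the morula address imprinting itself. The maternal share of Sfmbt2 reads was 0.800% and 0% in CTR (1 and 0 maternal reads; 95% exact Clopper-Pearson intervals 0.0203 to 4.38% and 0 to 2.18%). In matKO it was 17.2% and 14.8% (8.90 to 28.7% and 9.18 to 22.2%), a difference of 15.6 percentage points. Jade1 had 20.3% ± 0.104 (SD, n = 2) maternal reads in CTR and 40.5% ± 3.78 in matKO. Bbx had 11.5% ± 6.16 and 43.0% ± 6.1, and Xist 29.4% ± 14.1 and 65.8% ± 2.89. For each of these 4 genes both matKO libraries lay above both CTR libraries, for which an exact permutation test over 6 splits gives p = 0.333, the smallest this design allows. Gab1 had 35.8% ± 5.72 and 44.6% ± 3.91. Slc38a4 had 1.19% ± 1.68 and 3.82% ± 1.67, from at most 2 maternal reads per library, and Smoc1 34.4% ± 6.16 and 26% ± 8.49.

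Camera called the list of 6 core imprinted genes towards the maternal allele, with a median log2 change of the paternal to maternal ratio of −1.56 (adjusted p = 1.2e-06, and adjusted p = 0.0735 with an estimated correlation). Adjusted over the list alone 0 shifted towards the paternal and 4 towards the maternal allele, and Sfmbt2 (−5.45, SE 0.75) had adjusted p = 0.0846 over all genes. Smoc1 (0.50) lay on the paternal side, and neither it nor Slc38a4 passed. The 22 genes of the wider list had a median of −0.94, with 0 and 9 shifts to the paternal and maternal side adjusted over the list alone (adjusted p = 5.6e-09, and adjusted p = 0.0735 with an estimated correlation). Examples were Bbx (−2.52) and Epas1 (−1.39), a hypoxia factor. The 17 genes imprinted through DNA methylation had a median of −0.19 (adjusted p = 0.371). X-linked genes moved the other way: 221 of 232 had a positive change, with a median of 1.14 (adjusted p = 2.9e-50, and adjusted p = 0.0735 with an estimated correlation). Adjusted over the list alone 88 shifted towards the paternal and 1 towards the maternal allele, with Tktl1 (3.27), Pola1 (1.03) and Fundc1 (0.94) as examples. The paternal share of X-linked reads was 24.4% and 25.6% in CTR and 38.0% and 42.4% in matKO, while that of autosomal reads was 48.6 to 49.5%. By fry these 3 lists had adjusted p of 0.0179 to 0.0251.

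Over all 7637 genes of the allelic test, edgeR called 3, each towards the paternal allele, and 626 had an unadjusted p under 0.05. Magt1, an X-linked magnesium transporter gene, went from 88.4% and 90.8% maternal reads in CTR to 59.4% and 58.6% in matKO (2.56, SE 0.17, adjusted p = 0.0103). Lsm4, of the RNA processing complexes, went from 49.7% and 47.2% to 1.00% and 0.952% (6.38, SE 0.40, adjusted p = 0.0103), and Rab8a, a vesicle transport GTPase gene, from 55.0% and 51.2% to 28.5% and 25.3% (1.58, SE 0.14, adjusted p = 0.04996). Lsm4 and Rab8a lie on chromosome 8 between 69 and 76 Mb, where maternal reads of several genes were missing in matKO, and 1 call was left without that part. The count was 0 without CTR replicate 2, matKO replicate 1 or matKO replicate 2, and 3 without CTR replicate 1, of which 1 was shared. Pcgf6, a targeted gene whose maternal allele comes from the knockout oocyte, had 62.9% and 57.5% maternal reads in CTR and 46.6% and 40.9% in matKO (0.92, SE 0.18, adjusted p = 0.236).

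**Figure D2:**
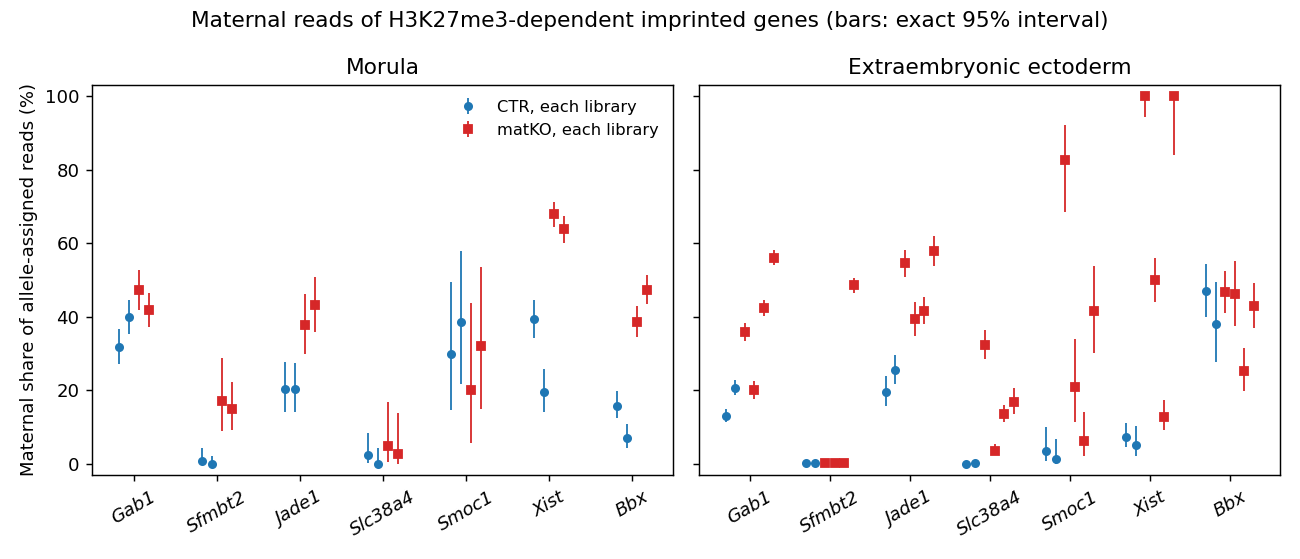
Maternal share of reads (percent) of 6 core imprinted genes and Bbx in each morula and ExE library, with 95% exact intervals; Bbx was added after its values were seen. Sfmbt2 lies at 0.800% and 0% in CTR morulae and at 17.2% and 14.8% in matKO morulae, and at 48.5% in 1 of the 4 matKO ExE libraries.

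The ExE comparison asks whether the effect of the maternal loss reaches the placental lineage after implantation. Pcgf1 had at most 1 allele-assigned read per library, so it checks nothing, and Pcgf6 had 292 and 278 CPM in CTR and 197, 178, 208 and 173 CPM in matKO. This is a mean of 285 ± 9.75 (SD, n = 2) against 189 ± 16.6 (n = 4) and did not pass over all genes (log2 −0.59, SE 0.13, adjusted p = 0.133). Its maternal share changed: 65.6% and 58.1% of reads were maternal in CTR and 35.5%, 43.8%, 25.97% and 42.0% in matKO (allelic log2 change 1.26, SE 0.14, adjusted p = 1.1e-05). The maternal allele of matKO embryos comes from knockout oocytes. A lower maternal share of this targeted gene is therefore what the genotype itself would give. Phlda2, which restrains placental growth, had 2439 ± 946 CPM in CTR and 752 ± 395 in matKO, and Eomes 64.2 ± 54.4 and 248 ± 81.2 CPM; neither passed.

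With edgeR 0 of 8386 genes were called in ExE, 1161 had an unadjusted p under 0.05, and the DESeq2 Wald test called 143 rises and 71 falls. The groups did not overlap for 1974 genes (23.5%), where chance gives 13.3% for a single gene, and again this share is no test. Without matKO replicate 3 edgeR called 6 genes, and without CTR replicate 1 it called 4. Core imprinted genes had log2 changes of 0.77 for Sfmbt2, 0.63 for Jade1, 0.34 for Gab1, −0.20 for Slc38a4, −0.21 for Smoc1 and −0.21 for Xist. Xist ranged from 6.09 CPM in matKO replicate 4 to 75.7 CPM in another matKO library. Replicates 1 and 4 of matKO held almost no paternal X-linked reads (0.146% and 0.154%), so the mean change of Xist cannot be read as no change.

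Groups of developmental genes were higher in matKO ExE, with 0 members called over all genes. Of 22 developmental transcription factors 18 were positive, with a median of 1.22, and 4 rose and 0 fell adjusted over the list alone (adjusted p = 3.6e-06, and adjusted p = 0.221 with an estimated correlation). Tbx18 had a log2 change of 4.0, Sox21 of 2.89 and Six2 of 1.99, and Zic2 had 1 and 54 counts (ratio 29.9, 95% exact interval 5.14 to 1202). Of 11 signalling genes 9 were positive, with a median of 0.85, and 3 rose and 0 fell adjusted over the list alone (adjusted p = 6.9e-05, and adjusted p = 0.292 with an estimated correlation). Fzd1 (3.37), Efnb2 (2.90) and Bmp8b (0.85), a signal from ExE to the epiblast, are examples, and Chrd had 0 counts in CTR and at least 4.61-fold more in matKO. The 12 pluripotency genes had a median of 1.98, with Lin28b (2.74), Fbxo15 (2.23), Klf5 (1.81) and Dppa4 (1.23), and 6 rose and 0 fell adjusted over the list alone (adjusted p = 2.2e-07, and adjusted p = 0.347 with an estimated correlation). Markers of 2 other tissues were higher beside these groups. The 8 epiblast and mesoderm markers were all positive, with a median of 1.72 and 0 calls adjusted over the list alone (adjusted p = 4.4e-05, and adjusted p = 0.347 with an estimated correlation). Pou3f1 had 2.76, Eomes 1.95 and Cdx1 1.49, and the mesoderm factor T had 2 and 67 counts (ratio 18.5, 4.94 to 156). Eomes is also on the trophoblast stem cell and ExE list, and Dnmt3b on that of the DNA methylation machinery. These 2 members therefore do not mark another tissue in ExE. The 5 visceral endoderm markers had a median of 0.73, with Rbp4 (2.51), Amn (2.22), Clu (0.73) and Lgmn (−0.06), and 2 rose and 0 fell adjusted over the list alone (adjusted p = 0.0166, and adjusted p = 0.347 with an estimated correlation).

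Trophoblast lists had medians of opposite sign in matKO ExE. For the trophoblast stem cell and ExE list the CTR libraries lay apart, at a median of 30.8 CPM in replicate 1 and 9.40 in replicate 2, against 41.6 to 69.5 in matKO. Its 19 tested genes had a median log2 change of 0.89, with Tead4 (1.25), a trophectoderm factor, Elf5 (0.47), Sox21 and Bmp8b, and 3 rose and 0 fell adjusted over the list alone (adjusted p = 3.6e-06, and adjusted p = 0.347 with an estimated correlation). The 8 genes of the ectoplacental cone and spongiotrophoblast had a median of −1.06, with Phlda2 (−1.70), Cited2 (−1.35) and Ascl2 (−1.30), and 0 calls adjusted over the list alone (adjusted p = 0.00184, and adjusted p = 0.374 with an estimated correlation). The 6 primitive endoderm genes had a median of 1.16, with Amn, Dab2 (1.52), Sparc (1.18) and Lamb1 (−0.76), and 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.00352, and adjusted p = 0.292 with an estimated correlation). The 21 imprinted genes of the wider H3K27me3 list had a median of 0.35, with Sh3gl3 at 2.01, and 2 rose and 0 fell adjusted over the list alone (adjusted p = 5.5e-04, and adjusted p = 0.221 with an estimated correlation). The 17 genes of the DNA methylation machinery had a median of 0.21, with Dnmt3l (0.89), Hells (0.69), Dnmt3b (0.48) and Mbd2 (−0.45), and 2 rose and 0 fell adjusted over the list alone (adjusted p = 0.0483, and adjusted p = 0.398 with an estimated correlation). The 19 p53 response genes had a median of 0.35, with Pmaip1 (1.37), Ccng1 (0.60), Mdm2 (0.49) and Plk2 (−2.25), and 0 calls adjusted over the list alone (adjusted p = 0.0387, and adjusted p = 0.398 with an estimated correlation). The epiblast, mesoderm and visceral endoderm markers above were higher in the same libraries. Over the 11 lists adjusted p was 0.221 to 0.398 with an estimated correlation and 0.0778 to 0.220 by fry, and the other 14 were not called (adjusted p = 0.355 to 0.981).

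Imprinted alleles in ExE differed from library to library. In matKO replicate 3, 64.9% of autosomal reads were paternal, against 48.5 to 48.8% in the other libraries. Jade1 had 19.6% and 25.5% maternal reads in CTR and 54.5%, 39.3%, 41.6% and 57.9% in matKO, a mean of 22.6% ± 4.18 (SD, n = 2) against 48.3% ± 9.22 (n = 4; exact permutation test, p = 0.0667, the smallest for this design). Slc38a4 had 0% (up to 0.593%) and 0.296% in CTR and 32.4%, 3.60%, 13.5% and 16.9% in matKO (exact permutation test, p = 0.2). Smoc1 had 3.57% and 1.23% in CTR and 82.6%, 21.1%, 6.33% and 41.7% in matKO (exact permutation test, p = 0.2). For Slc38a4 and Smoc1 each matKO library lay above both CTR libraries. The test compares group means, so the wide spread among the matKO libraries raises its p. Gab1 had 13.1% and 20.7% in CTR and 35.9%, 20.1%, 42.4% and 56.1% in matKO (exact permutation test, p = 0.267). Sfmbt2 stayed at 0.180 to 0.357% in 5 libraries and was 48.5% (95% exact interval 46.4 to 50.7%) in matKO replicate 4. Xist had 7.30% and 5.19% in CTR and 100%, 50.0%, 12.9% and 100% in matKO, the values of 100% from 62 and 21 reads (94.2 to 100% and 83.9 to 100%). Those 2 libraries held almost no paternal X-linked reads, so their Xist share says nothing on imprinting. The paternal share of X-linked reads was 3.99% and 3.47% in CTR and 0.146%, 43.0%, 38.7% and 0.154% in matKO.

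Camera called the list of 5 autosomal core imprinted genes towards the maternal allele in ExE, with a median of −4.54 (adjusted p = 2.0e-06, adjusted p = 0.0972 with an estimated correlation and 0.0455 by fry). Adjusted over the list alone 0 shifted to the paternal and 1 to the maternal side, and the value of Sfmbt2 (−4.85, SE 5.17) came from replicate 4 alone. The 15 genes of the wider list (median −0.24, mean −1.29, adjusted p = 0.0585) and 24 genes imprinted through DNA methylation (median −0.02, adjusted p = 0.743) were not called. For some of the latter the maternal share in several matKO libraries lay outside the CTR values. H19, chosen after its values were seen, had 99.8% and 99.7% maternal reads in CTR and 87.2%, 99.9%, 84.5% and 80.4% in matKO. Maternal reads of Peg3 made up 0% in both CTR libraries and 12.8%, 3.26%, 1.88% and 1.1% in matKO, and those of Mest 7.50% and 3.45% against 25.8%, 13.6%, 23.9% and 19.8%.

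Over 6857 autosomal genes edgeR called 5 allelic changes in ExE, and 435 had an unadjusted p under 0.05. Besides Pcgf6, a targeted gene, Tmem50b shifted towards the paternal allele (0.56, SE 0.11, adjusted p = 0.0245). Thoc1, of the mRNA export complex, went from 3.39% and 1.74% maternal reads in CTR to 50.3%, 53.6%, 37.1% and 50.6% in matKO (−5.39, SE 0.35, adjusted p = 2.7e-12). In CTR morulae Thoc1 had 40.2% and 52.9%. Whether strain variants alter the assignment of reads at Thoc1 and Platr20 in ExE was not tested, so these calls may not reflect expression. Platr20 (−3.01, SE 0.56, adjusted p = 0.0111) and Acaa2, an enzyme of fatty acid oxidation (−0.57, SE 0.10, adjusted p = 0.00329), shifted the same way. Tmem50b, Platr20 and Acaa2 lost their call without either CTR library, and Tmem50b without matKO replicate 1. Pcgf6 kept its call in each leave-out and lost it with equal offsets for both alleles. Those offsets gave 4 calls, of which 1 was among the 5, and the DESeq2 Wald test gave 4, of which 2 were. Without CTR replicate 1 the count was 8, of which 2 were shared, and without matKO replicates 2, 3 and 4 it was 13, 14 and 14, of which 5 were shared each.

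**Figure D3:**
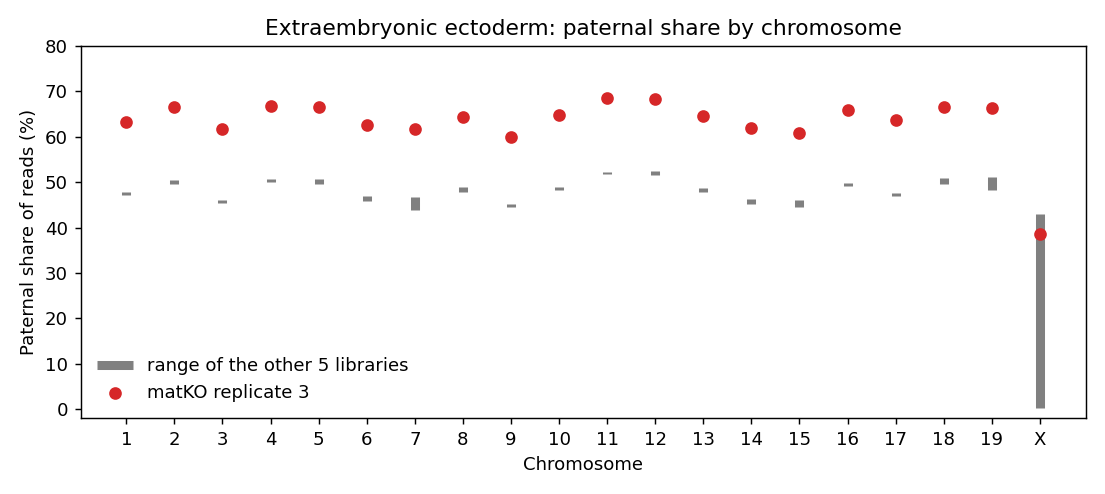
Paternal share of reads (percent) on each chromosome in ExE, with matKO replicate 3 in red and the range of the other 5 libraries in grey. On the autosomes replicate 3 lies above that range, with 64.9% over all autosomes against 48.5 to 48.8%.

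The differences between stages were tested as interaction terms. Between ExE and morula 38 of 11182 genes differed, 31 with a higher and 7 with a lower effect in ExE, and 1472 had an unadjusted p under 0.05. When each stage was fitted alone, 7236 genes passed the filter in both ExE and morulae. Dsc2 had log2 changes of −0.06 in ExE and −6.60 in morulae (difference 6.53, SE 0.55, adjusted p = 7.0e-05), and Mpnd of 0.16 and −5.64 (5.83, SE 0.85, adjusted p = 0.00993). Of 13 primitive endoderm genes 2 passed over all genes and 5 adjusted over the list alone, with a median difference of 1.77 (adjusted p = 4.6e-04, and adjusted p = 0.349 with an estimated correlation). Between morula and FGO 386 of 14719 genes differed, 56 with a higher and 330 with a lower effect in morulae, and 2339 had an unadjusted p under 0.05. With DESeq2 size factors 77 were higher and 238 lower, and the median of all genes moved from −0.07 to 0.08. When each stage was fitted alone, 8083 genes passed the filter in both FGO and morulae. A gene with few or no counts in 1 stage has no measured effect there, so a lower effect in morulae can mean too few reads. Mt1 had log2 changes of 0.27 in morulae and 7.08 in FGO (difference −6.82, SE 0.24, adjusted p = 2.1e-08), Tbl1x −0.91 and 6.31, and Plod2, a collagen-modifying enzyme gene, −0.41 and 6.07. Of the core imprinted genes, Jade1, Slc38a4, Smoc1 and Xist had too few counts in FGO for a difference to be read from them.

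Shared calls were limited in advance by the 12 genes called in morulae and 0 in ExE. Bbx rose in both FGO and morulae, the 1 gene shared of 357 and 2 rises among 8083 genes tested in both, where 0.0883 would be shared by chance (Fisher's exact test, p = 0.0864). No fall was shared between FGO and morulae, and ExE had no call with edgeR to share. Among the 500 rises and the 500 falls with the smallest p of each stage, 32 rises were shared by FGO and ExE against 14.01 by chance (Fisher's exact test, p = 9.2e-06). Of those 500 rises, 267 of FGO and 397 of ExE were among the 7566 genes tested in both stages. Falls shared by morula and ExE numbered 42 against 24.1 (Fisher's exact test, p = 3.2e-04), and falls shared by FGO and morula 21 against 10.6 (Fisher's exact test, p = 0.00328). The other 3 overlaps did not pass by Fisher's exact test: rises of FGO and morula (17 against 13.5, p = 0.318), rises of morula and ExE (23 against 19.98, p = 0.478) and falls of FGO and ExE (6 against 7.72, p = 0.707). Fisher's exact test treats genes as independent replicates, which they are not. Its p-values therefore do not measure the variation between libraries, and no shared effect of the knockout can be read from them.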

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

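The tests of explanations and of parental shares in this part were chosen after the results were seen, while the comparisons of CPM between single libraries and of effects between stages were planned. In the matKO group of ExE, 7 of 63 values had 1 library far from the other 3, where chance alone gives about 1 in 20 for a single value. The 63 values are not independent, so their number cannot be set against that rate. Paternal reads made up 64.9% of autosomal reads in replicate 3, against 48.5 to 48.8% in the other ExE libraries. Sfmbt2 had 48.5% maternal reads in replicate 4, against 0.180 to 0.357% in the rest. Maternal shares in replicate 3 were 18.6% for Tmem50b, 50.5% for Ube2cbp and 95.2% for Cdkn1c. These lower shares go with the paternal excess of that library and are not separate from it. Fzd1 had 22.5 CPM in replicate 1, and Lgmn had 773 CPM in replicate 3.

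The paternal excess of ExE matKO replicate 3 was tested against 3 explanations. Tissue of the paternal strain mixed into the sample would have to make up 31.6% of it. That argues against such tissue, since 9 maternally expressed imprinted genes, chosen after their reads were seen and without H19, held 7.13% paternal reads (95% exact interval 6.48 to 7.81%) and at most 15.9% in 1 gene. H19, left out of them, held 84.5% maternal reads there, and 87.2% and 80.4% in replicates 1 and 4. A gain of single paternal chromosomes is argued against by 19 of 19 autosomes lying above their highest share in the other libraries. An extra paternal genome stays open as a candidate explanation: the odds of paternal reads were 1.96 times those of the other libraries in the median over autosomes (1.85 to 2.00), within bounds of 1.7 to 2.3 that were set afterwards, and a biological effect of the maternal knockout stays open as untested.

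Maternal Xist reads in matKO morulae were 6.85 times those of CTR per maternal autosomal read, against 1.65 times for paternal Xist reads. More female embryos alone would leave the maternal share alike. The edgeR change of the paternal to maternal ratio was −2.13 (SE 0.41, adjusted p = 0.00793 over the 6 core genes and 0.273 over all genes). This argues against more females alone, but it rests on the same reads that raised the question and is no independent test. The maternal share also differed between the 2 CTR libraries (39.4% and 19.5%). Tsix reads counted as Xist reads stay open: maternal Tsix reads were 0.818 times those of CTR, with at most 21 per library, but how reads lying in both genes were counted is not given in the sources used here. A change of Xist imprinting after the maternal loss of Pcgf1 and Pcgf6 stays open as untested, with 2 libraries per group.

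The paternal share of X-linked reads in matKO morulae could come from more female embryos, because only females carry a paternal X chromosome. X-linked reads per autosomal read were 0.822 times those of CTR on the maternal allele and 1.61 times on the paternal allele. More female embryos and an effect of the knockout on X inactivation cannot be told apart here: the lower maternal level does not exclude more females, since the single X chromosome of males can be expressed more than each X chromosome of females, and the sex of the embryos is not given in the sources used here.

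Effects differed between stages by an interaction test in edgeR for 38 genes (ExE minus morula) and 386 genes (morula minus FGO). Both fits, and the lists below, include genes with few or no counts in 1 of the stages, whose difference rests on the other stage. The log2 differences between ExE and morula were 6.53 for Dsc2, 5.83 for Mpnd, 3.04 for Sft2d2, 2.86 for Cib2 and 2.67 for Slc9a3r1. Median differences over lists were 2.96 for epiblast and mesoderm markers, 1.77 for primitive endoderm, 1.72 for trophoblast stem cell and ExE genes, 1.18 for trophectoderm, 1.10 for developmental transcription factors, 0.74 for pluripotency genes and 0.46 for the DNA methylation machinery. They were −0.33 for ribosomal protein genes and −0.88 for immediate early genes, and over these 9 lists adjusted p was 0.349 to 0.579 with an estimated correlation.

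Between morula and FGO the log2 differences were −7.19 for Tbl1x, −6.82 for Mt1, −6.48 for Plod2, −6.10 for Ddah1 and −4.87 for Sgk3. Median differences over lists were −2.01 for the core and −0.94 for the wider imprinted genes with maternal H3K27me3, −1.38 for trophoblast stem cell and ExE genes, −0.89 for trophectoderm genes and 0.17 for ribosomal protein genes. In FGO 4 of the 6 core genes had too few counts to be tested. The core median therefore rests mostly on genes whose FGO change is not known, and no difference between stages can be read from it. Over these 5 lists adjusted p was 0.411 to 0.639 with an estimated correlation.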

How the results depend on the processing

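The tests on parental counts, without a part of chromosome 8 or without single ExE libraries, and all settings of the allelic test were chosen after the data were seen. In FGO 972 genes were called, and between 767 and 2029 with 1 replicate left out, 1630 without a filter on low counts. In morulae, against 12, the count was 54 with DESeq2 size factors, 208 with the DESeq2 Wald test, 489 without a filter, 19 at a mean of at least 1 CPM, 166 with all 14 libraries in 1 fit, 6 without X-linked and Y-linked genes, 68 from paternal reads only, 8 from maternal reads only (4 of the 12 among them), and 7 to 524 with 1 replicate left out. In ExE, against 0, it was 112 without a filter, 214 with the DESeq2 Wald test, 35 with all 14 libraries in 1 fit, 5 from maternal reads only, 1 without the 2 matKO libraries with almost no paternal X-linked reads, and 0 to 6 with 1 replicate left out. The difference between ExE and morula had 38 genes, 238 without a filter and 74 without ExE matKO replicate 3, of which 37 were shared. The difference between morula and FGO had 386, and 791 without a filter. The allelic test in morulae had 3 genes, 9 at a minimum of 10 reads, 14 with the DESeq2 Wald test, 1 without the part of chromosome 8, which holds the other 2, and 0 to 3 with 1 replicate left out; in ExE it had 5, and 4 to 14 with 1 replicate left out. Apart from that part of chromosome 8, the cause of these moves was not tested. Of the lists called by camera (11, 9 and 11), 0, 0 and 0 were called with an estimated correlation and 1, 0 and 0 by fry. Overlaps of the 500 rises and of the 500 falls with the smallest p were 17 rises and 21 falls for FGO and morula, 32 and 6 for FGO and ExE, and 23 and 42 for morula and ExE. Among called genes, 1 rise was shared by FGO and morula and no other gene by any pair of stages.

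With a block for the replicate number 2021 genes were called in FGO, 310 in morulae and 923 in ExE, and 12, 7 and 10 lists. The labels give no reason to pair libraries by number. Deviations of libraries with the same number correlated at 0.251 in FGO, 0.180 in morulae and 0.262 and 0.0807 in ExE, with fewer than 3 pairs per stage.

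For all genes that the naming rule picks, 586 values in FGO kept direction and side of the threshold, 11 passed newly and 36 no longer passed; in morulae 588, 65 and 22; in ExE 626, 72 and 0. No called value changed sign in any setting. Where a left-out replicate leaves 1 library in a group, that library is assumed to vary like the other group. The comparisons of reciprocal morulae and a term for sex from Y-linked reads were not run. A gene with 3 counts in a morula library stands at 1.78 to 2.31 CPM, so low genes were not detectable there.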

Other observations

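The tests and gene choices in this part were made after the values were seen. Maternal reads of several genes on chromosome 8, between 69 and 76 Mb, were few or missing in both matKO morula libraries. Summed over 2 libraries, maternal reads went from 188 to 2 for Lsm4, from 124 to 0 for Tpm4, a tropomyosin gene, from 52 to 0 for Fkbp8 and from 32 to 1 for Mrpl34, a gene of the mitochondrial ribosome. Over 22 genes the median log2 change was −0.68 for maternal and 0.35 for paternal reads. The gain of paternal reads made up 0.606 and 0.633 of the loss of maternal reads in the 2 matKO libraries. The difference of these medians was −1.03, and the lowest among 311 runs of as many genes on other autosomes was −0.39. The part of chromosome 8 was chosen for its missing maternal reads, so this comparison gives a size and is no test. In ExE, 14 of the genes had a median maternal change of −0.11, but the 4 genes named above had no parental reads there and are not among them. Whether strain variants of the B6.129 mothers alter the assignment of reads at these genes, or at Thoc1 and Platr20 in ExE, was not tested.

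Parental bias was followed over all autosomal genes with at least 20 reads in each library, imprinted genes among them. Of genes with at least 80% paternal reads in morula CTR replicate 1, 176 had a median paternal share of 84.9% in CTR replicate 2, 85.4% in matKO replicate 1 and 82.6% in matKO replicate 2. Of these, 14.2% lay below 60% paternal reads in CTR replicate 2 and 15.3% and 14.8% in matKO. Among 176 genes chosen in CTR replicate 2 it was 14.8% in CTR replicate 1 and 9.66% and 5.68% in matKO. In ExE, 109 genes chosen in CTR replicate 1 had a median of 89.6% in CTR replicate 2 and 87.8 to 94.9% in the matKO libraries, the highest in replicate 3. Below 60% paternal reads were 3.67% of these genes in CTR replicate 2 and 5.50 to 9.17% in the matKO libraries. Of 107 genes chosen in CTR replicate 2 these were 1.87% in CTR replicate 1 and 7.48%, 7.48%, 0.935% and 9.35% in matKO replicates 1, 2, 3 and 4, which was not tested. Maternally biased genes of ExE, 219 of them, had a median maternal share of 90.1% in CTR replicate 2 and 82.2% in matKO replicate 3. Bbx, whose maternal share in morulae was higher in both matKO libraries without passing the test over all genes, had 47.1% and 38.1% maternal reads in ExE CTR and 46.8%, 46.2%, 25.2% and 43.0% in ExE matKO. Maternal reads of Peg10 and Sgce, paternally expressed neighbours, were 0% in both ExE CTR libraries for Peg10, and 1.20% and 2.72% for Sgce. In ExE matKO replicates 1, 2, 3 and 4 they were 13.8%, 0%, 18.8% and 10.6% for Peg10 and 7.88%, 0%, 25.5% and 12.99% for Sgce.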
